A study of Homo sapiens with 2 samples.

How the data were processed

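RNA from 2 cultures of MIA PaCa-2 cells, an established human pancreatic cancer cell line, was compared: 1 labelled with a guide against GFP (control) and 1 labelled with a guide against TPST2. Per the labels' protocols, RNA was purified on silica columns and libraries were made with a stranded total RNA kit, so transcripts without a poly(A) tail were also captured. Per the submitters' processing notes, STAR and Cuffdiff were used with the build hg38; versions, the annotation release and the strand setting of the counting are not given in the sources used here, so overlapping genes on opposite strands may share reads in these values. The deposited table holds, per the file headers, 1 value per gene for each of the 2 cultures, a status, a p-value, a q-value and a log2 fold change. The header names no unit for the 2 value columns. They were read as FPKM (fragments per kilobase of transcript, scaled to library size), the unit in which Cuffdiff reports expression, and the authors' scaling between the libraries was kept. The values sum to 1.010e+06 in sgGFP and 1.001e+06 in sgTPST2. With sums this close, a scaling to a common sum is not excluded, and the unit stays an assumption. The authors' p-value and q-value are Cuffdiff's, and the dispersion setting behind them is not given in the sources used here. The authors' log2 fold change equals log2((sgTPST2 + 1)/(sgGFP + 1)) of the 2 value columns to within 2.1e-15.

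The table lists 58698 genes. All 58698 gene identifiers and symbols match the GENCODE release 29 annotation (GRCh38), and 58695 genes lie inside the locus the table gives for them; gene coordinates were taken from that annotation. By status, 18574 genes were tested by the authors (OK), 40112 were not (NOTEST), 8 were at loci too deep to estimate (HIDATA) and 4 failed (FAIL). The HIDATA locus on chromosome 14 holds the ribosomal protein gene RPS29 and the 7SL RNA gene RN7SL1, both named after their values were seen, listed at 0 in sgTPST2 and at 2833 and 84410 FPKM in sgGFP. A value of 0 at such a locus can therefore be a failed estimate, and genes at 0 are described only as listed at 0. Where a symbol occurs more than once, the entry with the higher mean was used for gene lists.

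Depth was read from the low values. In genes with a single annotated transcript longer than 1500 bp, values multiplied by the transcript length (less an offset of 190 bp in sgGFP and 180 bp in sgTPST2) clustered at whole multiples of 0.0236 FPKM per kb in sgGFP and 0.0209 in sgTPST2. Of 1019 such low values in sgGFP and 971 in sgTPST2, 90.8% and 91.7% lay within 0.1 of a whole number of fragments. Evenly spread values would give 20%. The step and the offset were fitted on these same values, so 20% is not the chance level of this procedure. A value of 1 FPKM thus stands for about 42.3 fragments per kb of transcript in sgGFP and 47.9 in sgTPST2. At 5 FPKM, a transcript of 1 kb rests on about 212 fragments in sgGFP, with a counting error of 6.88%. Such intervals cover counting error only.

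There was 1 sample per group, so no test was made, no difference has a replicate check, and no p-value of its own is given. Differences are log2((sgTPST2 + 1)/(sgGFP + 1)), a scale that understates the change of genes near 1 FPKM. Genes entered where the higher value was at least 1 FPKM, and 2-fold is counted on that scale. Before the data were examined, 41 gene lists were fixed, together with the rule for named genes: TPST2, TPST1 and SLC35B2; the 12 largest rises and 12 largest falls among genes with 1 symbol, a higher value of at least 5 FPKM and the status OK (leaving out symbols that start with SNOR, SCARNA, RNU, RN7S, MIR, RNY or Y_RNA, mitochondrially encoded genes and clone-based names; small RNA genes with other symbols stayed in the ranking); and up to 4 members per list with the largest absolute difference among those at 5 FPKM or more. Some genes that the rule names are not reported here. Genes and regions outside that rule are said to have been chosen after their values were seen. A list with at least 3 members past the filter is described by its median difference and by the percentile of that median among 10000 random lists of the same size, matched on deciles of mean expression. The percentile describes these 2 libraries and is not a p-value. Members at least 1.5-fold higher or lower are counted.

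Chromosomal position was examined after the values were seen, on 8567 protein-coding genes with status OK and a mean of at least 5 FPKM, in windows of 10 Mb with at least 10 genes (258 windows). The short arm of chromosome 12 was taken as genes ending at or before 35 Mb. On simulated data, lists of 20 genes drawn from 13371 genes with permuted differences fell outside the middle 95% of random lists in 4% of 100 draws with no planted shift, in 98% with a shift of 0.3 and in 100% with a shift of 0.6 (log2). A shift of -0.5 planted in 1 window of 54 genes among 8567 genes was recovered as the lowest window.

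Alternatives fixed before the data were examined were a pseudocount of 0.1, rescaling to the same upper quartile, centring on the median gene, scaling both columns to the same sum, no filter or a filter of 5 FPKM, a threshold of 1.5-fold, and 2 restrictions of the genes with q under 0.05 in the authors' deposited table. Chosen after seeing the data were the restrictions to protein-coding genes with status OK, to genes off the short arm of chromosome 12, to genes not listed at 0, and random lists of protein-coding genes. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.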

Results

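The study concerns tyrosine sulfation in pancreatic cancer: TPST2 is 1 of the Golgi enzymes that add sulfate to tyrosines of secreted and membrane proteins, and SLC35B2 carries the sulfate donor into the Golgi. Total RNA was sequenced from MIA PaCa-2 cells, a human pancreatic cancer line, carrying either a guide against GFP, which human cells lack, or a guide against TPST2. Each condition was a single library, so none of the differences below could be set against a spread between replicates. In the control, 10847 protein-coding genes reached 1 FPKM, and in sgTPST2 10756 did. From the size of the smallest steps in low values, the sgTPST2 library was the deeper, with 1 FPKM standing for about 47.9 fragments per kb of transcript against 42.3 in the control.

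TPST2 itself (ENSG00000128294.15, chromosome 22, 26521983 to 26596717, GRCh38) was lower in the cells with its guide. It stood at 8.46 FPKM in the control and at 1.92 FPKM in sgTPST2, a log2 difference of -1.70 on the log2(FPKM + 1) scale. For 1 kb of transcript these values stand for about 358 and 92 fragments, whose Poisson 95% intervals correspond to 7.61 to 9.39 FPKM and 1.55 to 2.35 FPKM and do not overlap; they cover counting error only. The labels describe these cells as a knockdown, and whether the guide led to a cut or to repression is not given in the sources used here, so the RNA level checks the label and does not measure how much TPST2 function was lost. In the authors' deposited table the gene has p = 0.00215 and q = 0.245, above the threshold of 0.05 used here. The paralogue TPST1 was at 14.2 and 16.2 FPKM, and SLC35B2 at 45.2 and 39.6 FPKM. Of 12 measured genes of tyrosine sulfation and sulfate donor supply, TPST2 alone was at least 1.5-fold lower and 0 were 1.5-fold higher (median 0.12, percentile 91.3 among random lists). Heparan and chondroitin sulfate synthesis genes had a median of 0.00 over 24 genes, with 1 gene 1.5-fold higher and 0 lower. The 8 measured proteoglycan core proteins had a median of -0.15 (percentile 4.10), and serglycin (SRGN) was the 1 member 1.5-fold apart, at 452 FPKM in the control and 708 in sgTPST2.

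Over all genes the libraries were close, and differences of protein-coding genes leaned towards lower values in sgTPST2. Of 13420 genes at 1 FPKM or more, 216 were at least 2-fold higher and 393 at least 2-fold lower, while 88.7% lay within 1.5-fold and the median difference was 0.00. The counts depend on the settings: 402 and 651 with a pseudocount of 0.1, and 127 and 241 among genes at 5 FPKM or more; without genes listed at 0, 139 were higher and 315 lower. Among 11048 protein-coding genes, 95 were 2-fold higher and 260 lower. The 251 small or structural RNA genes were far more scattered, with 38.2% within 1.5-fold, and went the other way, with 63 genes 2-fold higher and 50 lower (median 0.16), and of 717 pseudogenes 31 were higher and 35 lower. The 393 lower genes include the 5 HIDATA genes, listed at 0 in sgTPST2. The authors' deposited table calls 96 genes at its q threshold of 0.05, 17 of them higher and 79 lower. Of these 96, 23 stay under 1 FPKM in both libraries and 23 are listed at 0 in 1 library.

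**Figure D1:**
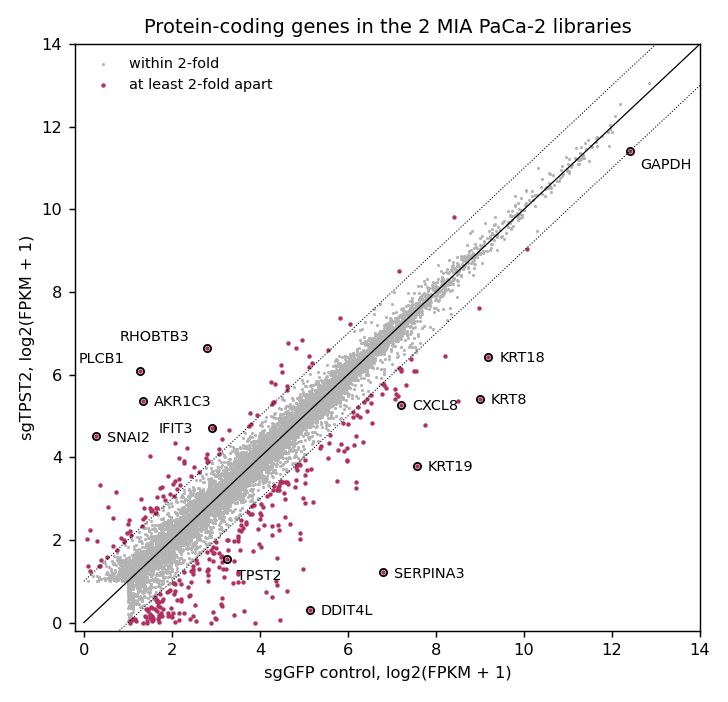
Each point is a protein-coding gene with status OK and at least 1 FPKM in 1 of the 2 libraries, at its log2(FPKM + 1) in the control (x axis) and in sgTPST2 (y axis). The solid line marks equal values, dotted lines mark 2-fold, and 95 genes lie 2-fold above and 258 2-fold below.

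The 12 largest falls included keratins and the secreted proteins SERPINA3, PTX3 and KLK6. The protease inhibitor SERPINA3 stood at 110 FPKM in the control and at 1.31 in sgTPST2, the pentraxin PTX3 at 20.9 and 0.0475, the kallikrein protease KLK6 at 23.3 and 0.686, and the protease inhibitor SPINT2 at 30.5 and 1.44. Among keratins, KRT19 stood at 189 and 12.8 FPKM, KRT8 at 510 and 41.6, and KRT15 at 20.02 and 0.884. DDIT4L was at 34.0 and 0.244 FPKM and the nuclear receptor gene NR5A2 at 18.3 and 0.538. The metallothionein MT1G was at 13.9 FPKM in the control and is listed at 0 in sgTPST2, as are the pseudogene TMSB4XP8 and the small RNA RF02039, whose symbol the ranking did not leave out. Of these 12, 6 pass q = 0.05 in the authors' deposited table, with q = 0.0126, the smallest q there, for SERPINA3, KRT19 and KRT8. The rest do not: KRT15 has q = 0.135, and PTX3, DDIT4L, SPINT2, TMSB4XP8 and RF02039 have q = 0.9997.

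Among the 12 largest rises, the phospholipase gene PLCB1 stood at 1.43 FPKM in the control and at 67.5 in sgTPST2. SNAI2, a transcriptional repressor of epithelial genes, stood at 0.211 and 21.7 FPKM. The aldo-keto reductase AKR1C3 was at 1.52 and 40.3 FPKM, RHOBTB3 at 5.92 and 99.0, and the homeobox gene HLX at 0.292 and 8.99. The glutaredoxin GLRX was at 1.84 and 15.2 FPKM, the G-protein subunit GNAI1 at 0.658 and 7.87, PRND at 3.18 and 19.3, and the small nucleolar RNA host gene SNHG25 at 15.8 and 199.7. GLRX lies within the span of RHOBTB3 on the opposite strand, so its value may hold reads of RHOBTB3, which was not tested. The small RNA RF02038 and the 5S pseudogenes RNA5SP187 and RNA5SP225 are listed at 0 in the control. RF02038 (142317830 to 142317920) and RF02039 of the largest falls (142318047 to 142318167) are neighbours on the same strand of chromosome 5. Their opposite zeros may therefore not be separate changes. Of these 12, 4 pass q = 0.05 in the authors' deposited table, where PLCB1 and GLRX have q = 0.9997 and SNAI2 q = 0.0964.

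Of the 41 lists, 39 had at least 3 members past the filter, and the medians of 16 lay outside the middle 95% of random lists. About 2.0 would by chance if the genes of a list varied independently of each other, as random lists take them to. Genes of a list may vary together, and lists share genes, so the 16 lists are not an excess measured against chance. Without a filter on low values, medians were -0.10 for epithelial markers, -0.084 for matrix genes, -0.20 for proteases, -0.077 for inflammatory genes, -0.058 for Wnt targets, 0.24 for YAP/TAZ targets, 0.40 for interferon response genes, 0.068 for nuclear-retained RNAs and 0.00 for fibroblast markers.

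Epithelial genes were lower. Of 11 epithelial markers, 7 were at least 1.5-fold lower and 0 higher (median -0.76, percentile 0.00). KRT18 stood at 583 FPKM in the control and 85.3 in sgTPST2, the desmosomal gene DSP at 7.33 and 3.18, and KRT8 and KRT19, given above, belong to this list. Mesenchymal markers did not move together: of 11 genes, 1 was 1.5-fold higher and 4 were lower (median 0.07, percentile 75.8; 0.23 over members at 5 FPKM or more). SNAI2 was the higher one, while the matrix protein gene SPARC was at 6.40 FPKM in the control and is listed at 0 in sgTPST2, TGFBI was at 9.89 and 4.92, and AXL at 12.2 and 17.2.

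Adhesion and matrix genes were lower in part. Of 8 integrin subunits, 3 were 1.5-fold lower (median -0.21, percentile 1.15): ITGA6 at 15.3 and 2.55 FPKM, ITGB4 at 8.33 and 1.46, and ITGA3 at 45.4 and 14.8, whereas ITGAV was at 27.1 and 39.0. Without a filter on low values the integrin median was 0.01. ITGA6 lies in a 10-Mb window of chromosome 2 (170 to 180 Mb) whose 26 genes had a median of -0.20. Of 19 laminins, collagens and other matrix genes, 7 were lower and 0 higher (median -0.29, percentile 0.03), with COL1A2 at 29.05 and 3.47 FPKM, COL17A1 at 92.0 and 27.5, and COL18A1 at 20.8 and 12.7. Among 11 extracellular proteases and inhibitors, 3 were lower and 0 higher (median -0.33, percentile 0.04), with the collagenase MMP1 at 15.0 and 4.68 FPKM and the urokinase receptor PLAUR at 15.1 and 5.27. Focal adhesion components had a median of -0.03 over 18 genes (percentile 27.3), with FERMT1 at 23.8 and 9.23 FPKM and LPP at 18.9 and 32.1.

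Inflammatory genes were lower and interferon-response genes higher. Of 16 NF-kappaB and inflammatory genes, 8 were 1.5-fold lower and 0 higher (median -0.64, percentile 0.00); the chemokine CXCL8 stood at 146 FPKM in the control and 37.4 in sgTPST2, CXCL1 at 140.3 and 43.6, CXCL5 at 20.4 and 8.50, and the cytokine LIF at 20.8 and 9.44. With members at 5 FPKM or more alone, that median was -0.31. Of 26 interferon response genes, 13 were higher and 0 lower (median 0.62, percentile 100). IFIT3 stood at 6.56 and 25.2 FPKM, OASL at 1.44 and 6.98, IFIT2 at 7.41 and 17.5, and IFIT1 at 19.03 and 39.2. The authors' deposited table gives q = 0.9997 for IFIT1, IFIT2 and IFIT3 and q = 0.177 for OASL. Of 15 antigen presentation genes, 5 were higher and 0 lower (median 0.42, percentile 100), with CD274 (the checkpoint ligand PD-L1) at 2.17 and 7.22 FPKM, the immunoproteasome subunits PSMB9 at 4.70 and 12.5 and PSMB8 at 5.12 and 11.53, and HLA-B at 12.9 and 26.9.

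Targets of NRF2, the transcription factor of the oxidative stress response, were higher as a group. Of 20 genes, 8 were 1.5-fold higher and 0 lower (median 0.52, percentile 100). AKR1C1 stood at 336 FPKM in the control and 903 in sgTPST2, AKR1C2 at 19.4 and 53.4, and the cystine transporter SLC7A11 at 6.79 and 25.3. The AKR1C genes are similar in sequence, AKR1C1 and AKR1C2 most of all, so reads may be split between them with error. IFIT1, IFIT2, IFIT3 and the AKR1C genes lie on chromosome 10, whose 346 genes were 1.15-fold higher at the median. YAP/TAZ targets had a median of 0.40 over 14 genes (percentile 100), with 4 higher and 2 lower. AMOTL2 stood at 34.1 and 64.1 FPKM, ARHGEF17 at 3.61 and 7.28, NT5E at 76.2 and 30.4, and TEAD4, on the short arm of chromosome 12, at 34.0 and 21.4.

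ERK pathway output genes were lower in part, with 4 of 18 at least 1.5-fold lower and 0 higher (median -0.22, percentile 0.08). The ERK phosphatase gene DUSP6 stood at 11.3 and 0.958 FPKM, ETV4 at 10.6 and 3.71, EPHA4, in a 10-Mb window of chromosome 2 (220 to 230 Mb) whose 15 genes had a median of -0.49, at 89.8 and 55.8, and EMP1, on the short arm of chromosome 12, at 87.7 and 43.9. Of 9 Notch pathway genes 4 were 1.5-fold lower, but the median lay at the edge of the middle 95% of random lists (-0.21, percentile 2.51, or 2.42 and outside it without 12p genes, those of the short arm of chromosome 12) and was -0.065 over members at 5 FPKM or more, with the ligand JAG1 at 19.8 and 1.95 FPKM and HES1 at 16.1 and 4.15. Of 6 Wnt/beta-catenin targets 2 were lower (median -0.34, percentile 0.59), among them DKK1 at 40.3 and 22.2 FPKM. TGF-beta response genes went both ways, with 2 of 13 higher and 4 lower (median 0.13, percentile 95.6, inside the middle 95%): PMEPA1 stood at 24.6 and 4.22 FPKM, LTBP2 at 8.70 and 2.99, BAMBI at 4.06 and 17.6, and ID2 at 105 and 206.7. ER stress genes had a median of -0.18 over 17 genes (percentile 0.42), with 1 gene, HSP90B1, 1.5-fold lower at 190.9 and 125.7 FPKM.

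Proliferation and housekeeping lists stayed close to 0. None of 29 G1/S genes (median 0.02) and none of 31 G2/M genes (median 0.00) was 1.5-fold apart. The same held for 54 ribosomal protein genes (median -0.03) and 13 heat shock genes (median -0.04). Respiratory chain subunits encoded in the nucleus had a median of 0.00 over 35 genes, with NDUFA9, on the short arm of chromosome 12, as the 1 gene 1.5-fold lower. Glycolysis and hypoxia genes had a median of 0.00 over 27 genes, yet 5 were 1.5-fold lower, 3 of which (GAPDH, TPI1 and ENO2) lie on that arm; VEGFA was at 33.5 and 20.8 FPKM. Medians also lay inside the middle 95% of random lists for p53 targets (-0.11), apoptosis regulators (-0.03), ATF4 and amino-acid response genes (0.00), cholesterol synthesis (-0.08), fatty acid synthesis (-0.04), immediate early genes (-0.07), lysosome and autophagy genes (0.10; outside it without 12p genes, at percentile 98.3) and Golgi and secretory genes (0.06). Cholesterol synthesis had 4 of 22 genes lower, including HSD17B7 at 32.6 and 11.95 FPKM. Of 15 immediate early genes 5 were lower, including KLF4 at 8.46 and 3.01 FPKM and JUN at 19.9 and 8.17.

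Among lists that mark RNA handling, the 13 mitochondrially encoded proteins had a median of -0.50 (percentile 0.00), with 3 of the 13 at least 1.5-fold lower and 0 higher, and MT-CO1 at 353 and 234 FPKM. Nuclear-retained RNAs had a median of 0.18 over 11 genes (percentile 97.9), with 1 gene 1.5-fold higher and 0 lower. Replication-dependent histones had a median of 0.17 over 13 genes (percentile 98.3), with 0 genes 1.5-fold higher and 1 lower, HIST1H1D at 318 and 195 FPKM. Markers of other cell types were few. Of 3 fibroblast markers past the filter all 3 were lower (median -0.76, percentile 0.40), and all 3 are matrix or contractile genes (COL1A2, COL3A1 and, named after its values were seen, ACTA2). The 3 leukocyte markers had a median of -0.41 (percentile 6.14) and the 3 neuroendocrine markers one of -0.26 (percentile 7.78), with SCG2 at 33.4 and 86.9 FPKM. Both endothelial markers past the filter were lower, too few for a median: EMCN at 9.64 and 0.136 FPKM and, named after its values were seen, CDH5 at 2.93 and 0.277, and 0 acinar or islet markers passed it. EMCN (100395341 to 100880126) lies near DDIT4L of the largest falls (100185870 to 100190782) on chromosome 4. Whether the falls of EMCN and DDIT4L are separate changes was not tested.

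**Figure D2:**
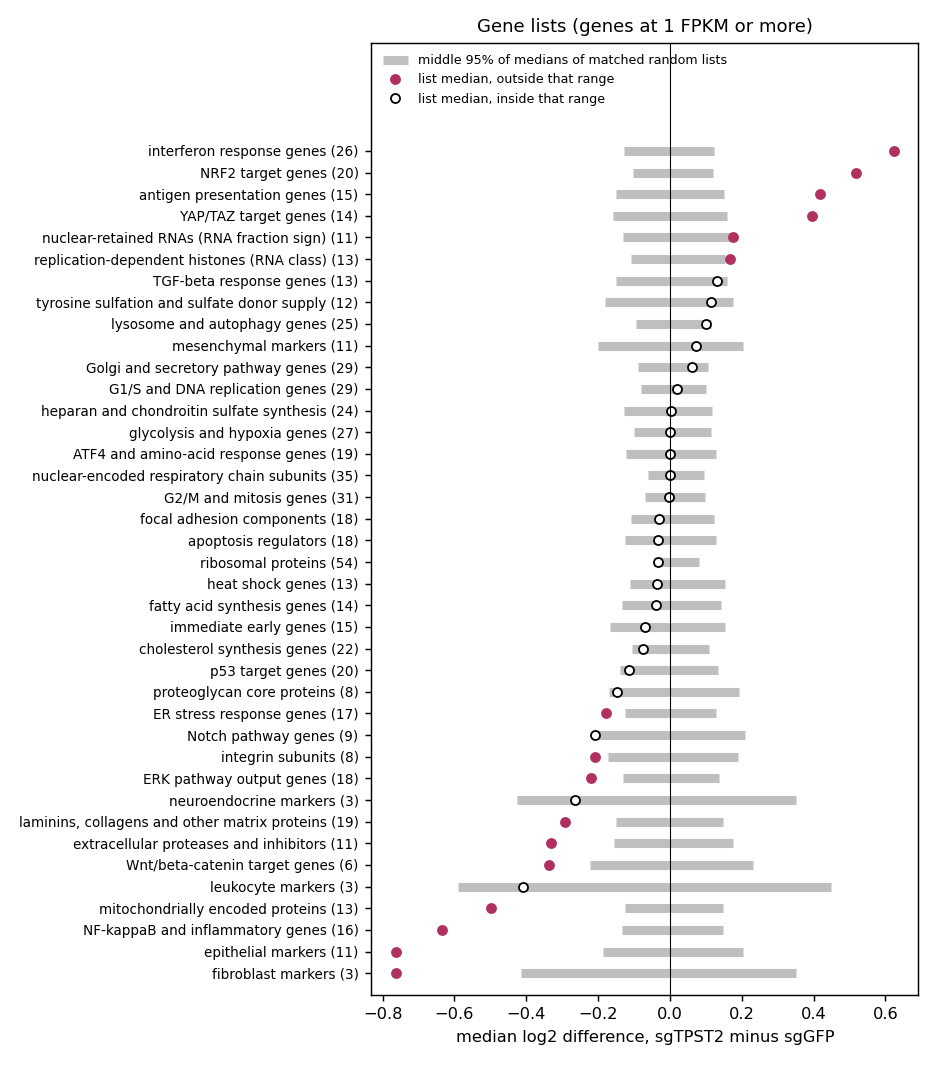
Median log2 difference (x axis, sgTPST2 minus sgGFP) of each of 39 gene lists, with the number of measured genes in parentheses; the grey bars hold the middle 95% of medians of 10000 random lists matched on expression. Interferon response genes (0.62) and NRF2 targets (0.52) lie farthest to the right, and epithelial (-0.76) and fibroblast markers (-0.76) farthest to the left.

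A whole chromosome arm was lower, a comparison made after the values were seen. Of 102 protein-coding genes on the short arm of chromosome 12 (12p, up to 35 Mb) with a mean of at least 5 FPKM, 100 were lower in sgTPST2 and 99 were at least 1.2-fold lower. Their median log2 difference was -0.88, which is 1.84-fold lower, and the median of the other 335 genes of chromosome 12 was -0.01. The change lay between ALG10, which starts at 34022281 and stood at 10.8 and 4.16 FPKM, and CPNE8, which starts at 38646822 and stood at 14.1 and 15.0. The 4 lowest of 258 windows of 10 Mb in the genome were the 4 windows from 0 to 40 Mb of chromosome 12, with medians from -1.07 to -0.83. The arm holds GAPDH, at 5414 and 2704 FPKM, TPI1 at 1246 and 715, ENO2 at 14.5 and 3.81, NDUFA9 at 171 and 81.6, the TNF receptor gene TNFRSF1A at 112 and 63.9, LTBR at 85.0 and 41.6, CD9 at 157 and 52.5 and YBX3 at 186 and 66.6. Of the 258 protein-coding genes with status OK that were 2-fold lower, 47 lie on 12p, and 0 of the 95 that were 2-fold higher do. Weaker shifts went both ways. On the long arm of chromosome 2, 104 genes from 190 to 230 Mb had a median of -0.33, while the window from 230 to 240 Mb was at -0.10 (38 genes). The highest window was that from 190 to 200 Mb of chromosome 3, with a median of 0.32 over 35 genes, and the 346 genes of chromosome 10 had a median of 0.20.

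**Figure D3:**
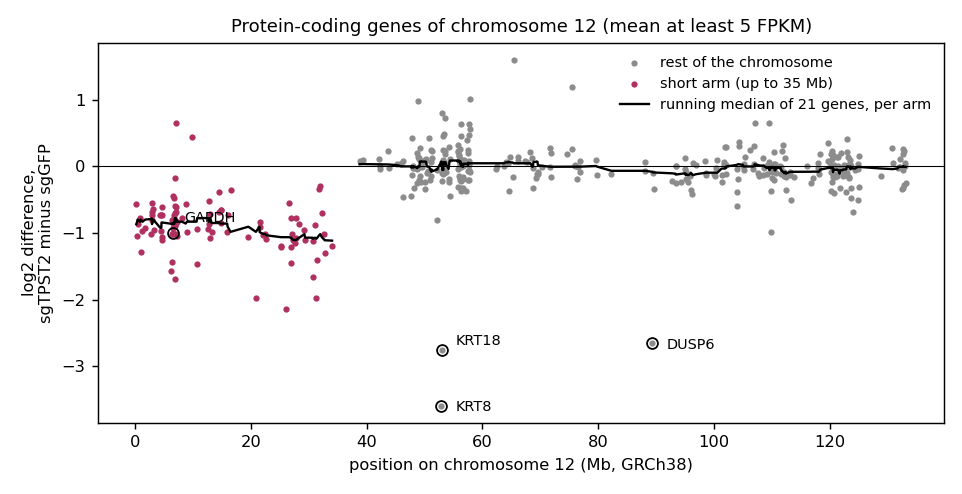
Log2 difference (y axis, sgTPST2 minus sgGFP) of each protein-coding gene of chromosome 12 with a mean of at least 5 FPKM, against its position in Mb (x axis, GRCh38); the black line is a running median of 21 genes within each arm. The 102 genes up to 35 Mb have a median of -0.88, and the 335 beyond it a median of -0.01.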

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

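No paired analysis was possible because each condition is a single library, and for the same reason no replicate could be left out. Rescaling to the same upper quartile, centring on the median gene and scaling both columns to the same sum moved none of the 42 counts, differences and list medians compared past its bounds (a count by 1.5 times, TPST2 outside its counting interval, a list median by 1 SD of random medians). Those rescalings are close to no change. The median difference of genes past the filter was -0.00019 as deposited, 0.0022 with the same upper quartile and 0.0115 with the same sum. Shifts this small could hardly pass the bounds, so the result says little about scaling. The sums took in the HIDATA locus, with RN7SL1 at 84410 FPKM in sgGFP and listed at 0 in sgTPST2. Scaling to sums without that locus was not tried, so the same-sum comparison does not cover it. With a pseudocount of 0.1, 402 genes were 2-fold higher and 651 lower, TPST2 differed by -2.09, and medians were -0.38 for matrix genes, -0.95 for epithelial markers, 0.74 for interferon response genes, -0.74 for inflammatory genes and -1.15 for fibroblast markers; these are larger because the smaller pseudocount shrinks low genes less. At 5 FPKM or more, 127 genes were 2-fold higher and 241 lower, and medians were 0.23 for mesenchymal markers, -0.995 for epithelial markers, 0.038 for apoptosis regulators, 0.71 for interferon response genes, -0.31 for inflammatory genes and -0.065 for Notch genes. With a threshold of 1.5-fold, 592 genes were higher and 931 lower. Without a filter, lists take in members near 0 in both libraries, which pulls medians towards 0 by construction: 0.00 for proteoglycans and for fibroblast, leukocyte and neuroendocrine markers, -0.084 for matrix genes, -0.20 for proteases, -0.10 for epithelial markers, 0.24 for YAP/TAZ targets, 0.40 for interferon response genes, -0.077 for inflammatory genes, -0.058 for Wnt targets, -0.039 for Notch genes and 0.068 for nuclear-retained RNAs, while integrins changed sign to 0.015. The other restrictions were chosen after seeing the data. Protein-coding genes with status OK gave 95 higher and 258 lower genes, and without 12p 95 and 211; fewer genes enter. Without genes listed at 0, 139 genes were higher. Without 12p genes, lysosome genes moved to percentile 98.3 and Notch genes to 2.42, outside the middle 95%, and 78 of 80 comparisons stayed within bounds. The counts of genes with q under 0.05 in the authors' deposited table stayed within 1.5 times under each of the 4 restrictions. Counting error is small at 5 FPKM, but variation between cultures, which these 2 libraries do not measure, limits every difference.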

Other observations

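Gene families outside the fixed lists were looked at after their values were seen, among members at 0.3 FPKM or more. Of 8 HOXB genes on chromosome 17, 7 were at least 1.5-fold lower in sgTPST2 (median -1.49). Among 3 HOXA genes (median -0.14) and 3 HOXC genes (median 0.20), 0 were 1.5-fold higher or lower. Those genes were low, the highest being HOXA3 at 1.94 and 1.67 FPKM. HOXB6 stood at 4.88 FPKM in the control and 0.0282 in sgTPST2, HOXB8 at 4.60 and 0.117, and HOXB9 at 4.31 and 0.0522, whereas HOXB13, at the far end of the cluster, was at 2.60 and 2.39. Of 5 kallikreins on chromosome 19, 4 were at least 1.5-fold lower, and KLK10, at 0.338 and 0.168 FPKM, is too low to reach that bound on the log2(FPKM + 1) scale; KLK6 stood at 23.3 and 0.686 FPKM, KLK7 at 1.85 and 0.0723 and KLK8 at 2.40 and 0.112. Of 4 guanylate-binding proteins, interferon-induced GTPases on chromosome 1, 3 were at least 1.5-fold higher, with GBP1 at 0.457 and 5.97 FPKM and GBP2 at 2.44 and 8.77, and GBP4, at 0.00398 and 0.396, rose from near 0 but stayed under that bound on this scale. Metallothioneins split: MT1G was at 13.9 FPKM in the control and MT1F at 0.873, both listed at 0 in sgTPST2, while MT2A was at 486 and 479, MT1E at 937 and 926 and MT1X at 259 and 264.

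Of the tests that follow, the correction for GC content and transcript length was written down before its result was seen, and the others were chosen after. The first pattern is the lower level of 12p genes in sgTPST2 (median -0.88). Library-wide scaling or depth would shift the rest of chromosome 12 too, and its median was -0.0056. After a trend on GC content and length fitted on other genes was removed, the arm's median was -0.898 (spread of the median 0.0489). A library from another line with an intact 9p21 region would show CDKN2A, CDKN2B or MTAP, and these are listed at 0.0 FPKM in both libraries, as are all 22 protein-coding genes from 21 to 23 Mb of chromosome 9, most of them interferon genes. They carry the status NOTEST, not that of a failed estimate, and of 149 ribosomal, respiratory chain and cell cycle genes 0 are at 0 in either library with such a status. The zeros of CDKN2A, CDKN2B and MTAP argue against such a line, while one that also lacks the region stays open. On the log2(FPKM + 1) scale, 90.9% of 11048 protein-coding genes lay within 1.5-fold. That scale understates changes of low genes, and no share for 2 different lines was at hand. The figure therefore does not decide whether a line lacking the region was involved. The spread within the arm was 1.23 times that of other genes around its shifted median. Any cause that acts evenly along the arm would give this, so the value does not single out a copy-number change. Fewer copies of 12p per cell in the sgTPST2 culture stays a hypothesis, since DNA was not analysed here. An effect of the guide and a difference between cultures cannot be separated with 1 library each.

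The second pattern is that more protein-coding genes were 2-fold lower (258) than higher (95). A shallower sgTPST2 library would list more genes near 0, yet 1 fragment was worth 0.877 times as much FPKM there as in the control, so that library is the deeper. Without 12p genes the ratio of lower to higher genes was 2.22 (211 against 95), and without genes listed at 0 in either library it was 2.66 (253 against 95). At the low end, 72 protein-coding genes were under 0.05 FPKM in sgTPST2 and above 0.3 FPKM in the control, against 17 the other way round. Whether the guide, or the loss of some of the cells that the control culture held, lies behind this was not tested.

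The third pattern is the low keratin level, with KRT8, KRT18 and KRT19 summing to 1282 FPKM in the control and 139.7 in sgTPST2. These genes have many pseudogenes, to which reads could be assigned in their place, yet the 123 pseudogenes of the 3 genes summed to 17.1 FPKM in the control and 12.8 in sgTPST2, a change of -4.25. Keratin-rich cells of another line that expresses MTAP, mixed into the control library, would bring MTAP. It is listed at 0.0 FPKM there, with the status NOTEST described above, which argues against such a line; a line without MTAP stays open. An effect of lower TPST2 stays open, as does a difference between the 2 cultures that has nothing to do with the guide.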
